A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

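Expression was measured on 2-colour yeast arrays, on which RNA of a culture and RNA of a reference were labelled with different fluorescent dyes and hybridised to the same probes. Per the labels, the strain was Saccharomyces cerevisiae W303-1A, a haploid MATa laboratory strain, grown in YEPD, a rich medium (glucose and bactopeptone at 20 g/l each, yeast extract at 10 g/l), with shaking at 110 rpm and a temperature of 30 °C. Cells of an unstressed parent culture in late exponential phase were used to start 3 separate cultures without ethanol and 3 with 6.5% (v/v) ethanol, so the 3 arrays of a group were separate cultures. The time in ethanol and the cell density at harvest are not given in the sources used here. RNA was taken from equal numbers of cells, treated with DNase and labelled indirectly with AlexaFluor 647 (red) or AlexaFluor 555 (green). Each of the 6 cultures was hybridised on 1 array against a pool of RNA of the 3 cultures without ethanol. In each group the pool was red on the array of culture 1 (dye-swapped), and the culture was red on the arrays of cultures 2 and 3.

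The authors deposited 1 table with a log2 ratio for each of 6368 probes on each of the 6 arrays, without missing values. The scanner, the background correction, the normalization, the filter on dim spots and the direction of the ratio are not given in the sources used here, and no intensity was used here, so signal over background is unknown. From the values, the scale was log2: they were bounded at 6.64 on both sides, which is the log2 of a ratio of 100, and a value at that limit is a bound. The median of the deposited log2 ratios lay between 0.01 and 0.04 on all 6 arrays, and the SD across probes between 0.64 (0% culture 1) and 1.20 (6.5% culture 1).

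The direction was taken as red over green. This is likely and not stated: after the mean of the 0% columns was subtracted, the swapped 6.5% array ran against the other 6.5% arrays (r = −0.28 and −0.25 across probes, which are not independent replicates, with r = 0.84 between the arrays that were not swapped), as the dyes in the labels require, but this holds for either direction. Of 205 probes beyond 4-fold in the same direction on 6.5% cultures 2 and 3, 122 had the opposite sign on culture 1. Across features the contrasts of the swapped and of the other arrays correlated at r = 0.42, and the dye term was called for 2155 features. The basis for the direction is the usual order of red over green, with which the stress genes HSP12 and HSP26 are higher in ethanol. If the ratios were green over red, every direction given would be opposite. The swapped arrays were multiplied by −1, which turned all values to culture over pool. After turning, 6.5% culture 1 correlated at r = −0.06 and −0.10 across probes with 6.5% cultures 2 and 3, against 0.85 between those 2. With the trend along the probe number removed, as described below, these values were 0.10, 0.04 and 0.84. Before the dye term was fitted, this ethanol array thus agreed little with the other 2.

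Probes were named from the platform annotation, with symbols updated by gene identifier through the RefSeq table of assembly R64. A single gene was given for 5673 probes, all of which matched that table. No probe had several genes and 695 had none. Probes without a gene were kept as features of their own, and the probes of the 23 genes with more than 1 were averaged, of which 14 had probes more than 1 log2 unit apart on some array. This gave 6345 features, 5650 of them named genes.

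The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays as 6.5% minus 0% ethanol, with dye orientation as a further term and 3 residual degrees of freedom. The pool cancels in this contrast. The two-sided p-values were adjusted by the Benjamini-Hochberg method over all features, and a feature was called at an adjusted p below 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with camera's estimated correlation and with fry. Before the data were examined, 40 lists were fixed from general knowledge of yeast. Of their 1523 names 1509 were measured. The 4 alpha-cell markers were too few for the list test, which needed 5 genes, and 39 lists were tested. Lists overlap, so their tests are not independent. Also fixed then was the rule for naming genes: the 10 largest increases and decreases among called genes with a standard name whose 6.5% arrays all lay beyond the 0% mean in the same direction, up to 2 leading members of each list that passed with 1 called member of the other direction, and 16 genes of ethanol and stress physiology whatever their values. The rule named 68 genes. Any other gene named was chosen after its values were seen.

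The test was checked on 20 simulated data sets for this comparison, each with 200 of 6345 features changed. It recovered 0.2% of the features changed by 0.5 log2 units, 9.7% at 1, 90.6% at 2 and 98.2% at 3. Of the calls 6.80% were false. In these data sets, with 3 arrays per group, most changes under 2-fold were therefore out of reach. They held independent noise, no trend along the probes and fewer changed features than were called in the data. Both the recovered and the false shares may thus differ in the data.

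Probe numbers largely follow the systematic gene names, and so the genes within each chromosome arm. On every array the deposited ratios rose with probe number (Spearman rho from 0.22 to 0.54 across probes). The size of this trend differed between arrays, so it did not cancel in the comparison. The fit to the values as deposited was kept, and beside it a fit is given in which a running median over neighbouring probes was subtracted from each array before the ratios were turned. This alternative was chosen after the data were seen. It also removes part of any real change shared by neighbouring genes.

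The other alternatives fixed beforehand were no dye term, the replicate number as a block, each array left out in turn, arrays centred on their medians, arrays also scaled to equal spread, quantile normalization, the 6.5% arrays against the pool alone, robust eBayes, array weights, other rules for genes with several probes or missing values, a change of at least 2-fold, and camera on ranks. Added later were other widths of the running median, the trend removed together with other choices, the arrays that were not swapped alone, and a repeated highest value of 1 array set to missing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No deposited column was left out.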

Results

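Genome-wide transcript levels were measured in 6 yeast cultures, 3 without ethanol and 3 with 6.5% (v/v) ethanol in the medium, to ask which genes differ in expression under ethanol stress. Each culture was compared on 1 array with a pool of RNA of the cultures without ethanol. Values are log2 ratios of culture over pool, and each change is the 6.5% minus the 0% cultures with its SE from limma (n = 3 arrays per group, on which the precision depends). All signs assume that the deposited ratios are red over green, which is likely but not stated. Higher HSP12 and HSP26 in ethanol were part of the basis for this, so the direction of the stress genes is not an independent result.

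Ethanol was accompanied by higher transcript levels of many stress genes and lower levels of many genes of ribosome production and sterol synthesis. The lists of these genes passed camera with its preset correlation, but no list passed with the correlation estimated from the arrays (lowest adjusted p = 0.225). With an estimated correlation camera tests on the 3 residual degrees of freedom, which leaves little power over 39 lists. Failing in that setting therefore decides little about any list. Where the estimated correlation was high, as given below, the p-value at the preset correlation may be too small. HSP12, which codes for a small membrane-associated stress protein, rose by the most. It read 6.64 on all 3 arrays with ethanol, the upper limit of the table, so that its change of 6.92 ± 0.40 is a lower bound (adjusted p = 0.00246). HSP26, a small heat shock protein that binds unfolded proteins, rose by 5.33 ± 0.33 or 40.2-fold (95% interval 4.53 to 6.12, adjusted p = 0.00246). TDH1, a minor isozyme of glyceraldehyde-3-phosphate dehydrogenase, rose by 5.58 ± 0.97 (adjusted p = 0.0147), but its value on the array of 0% culture 1 was among the 19 probes that shared the highest value of that array, and without that value it rose by 3.86. CHA1, the enzyme that breaks down serine and threonine, rose by 3.95 ± 0.25, SNZ1 of vitamin B6 synthesis by 3.79 ± 0.65 (from 2.98 to 4.50 with 1 array left out, the 0% arrays reading 0.30, −3.31 and −1.16), and HSP31, a chaperone and methylglyoxalase, by 3.79 ± 0.28. GPM2, a homologue of phosphoglycerate mutase, rose by 3.37 ± 0.30 and AHP1, a peroxiredoxin, by 3.25 ± 0.28. RGI1, which is linked to respiratory growth, and ULI1 rose by 3.21 ± 0.26 and 3.21 ± 0.25. Adjusted p-values of these last 7 genes lay between 0.00246 and 0.0146.

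As deposited the largest decrease was that of INA1, at −4.60 ± 1.09 (adjusted p = 0.0322), with the array of 6.5% culture 3 at the lower limit of the table. Its call was unsteady, being lost in 4 of the 6 fits without 1 array (with a change of −3.35 without 6.5% culture 3) and without the dye term (adjusted p = 0.104). With the probe-order trend removed INA1 was at −4.23 and FET3 at −4.25. FET3, the multicopper oxidase of high-affinity iron uptake, fell by 4.29 ± 0.35 (19.6-fold, 95% interval −5.13 to −3.46, adjusted p = 0.00499). DBP2, an RNA helicase of ribosome assembly and mRNA decay, fell by 4.05 ± 0.34 and OLE1, the fatty acid desaturase, by 3.58 ± 0.30, or 11.9-fold (adjusted p = 0.00499 for both). Among enzymes of purine metabolism, GUA1 (GMP synthase) fell by 3.40 ± 0.42 and AAH1 (adenine deaminase) by 3.32 ± 0.52. SVS1, a cell wall protein gene, fell by 3.33 ± 0.36, BAR1, the protease that degrades alpha factor, by 3.27 ± 0.28, and PDR12, the plasma membrane exporter of weak acids, by 3.21 ± 0.32. NTE1, a phospholipase, changed by −3.37 ± 0.80 (adjusted p = 0.0326). On NTE1 the arrays of 0% cultures 2 and 3 read 2.88 and 3.43 although the pool held RNA of these same cultures, and its adjusted p was 0.0702 once the probe-order trend described with the counts of genes was removed. The array of 0% culture 2 also read high on SVS1 and PDR12, at 2.26 and 1.88.

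**Figure D1:**
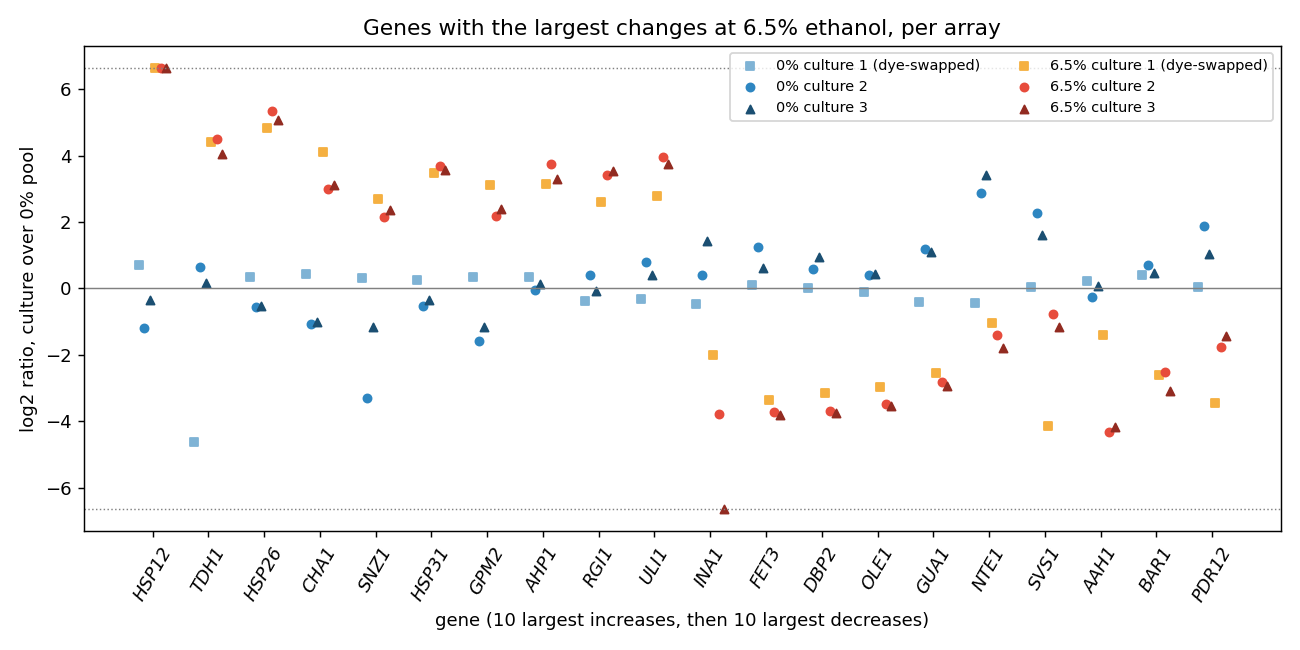
Log2 ratio of culture over pool (vertical axis) on each of the 6 arrays for the 10 genes with the largest increase and the 10 with the largest decrease (horizontal axis), with a point per array and dotted lines at the limits of the table. HSP12 lies at 6.64 on all 3 arrays with ethanol, and TDH1 stands at −4.61 on the array of 0% culture 1.

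Over all 6345 features, 1150 were called, of which 488 rose and 662 fell with ethanol, and 1075 of them changed at least 2-fold. The median change of all features was 0.04. The deposited ratios carried a trend along the probe number that differed between arrays, and with it removed 815 features were called, 368 higher and 447 lower. Both analyses, which use the same arrays, called 685 features, each in the same direction. In the values as deposited, 117 of the 634 features with the lowest probe numbers rose and 22 fell, against 31 and 134 of the 635 with the highest. With the trend removed these counts were 33 and 45 at the lowest and 50 and 56 at the highest probe numbers. The number of calls changed with single arrays. Without 6.5% culture 2 only 2 features were called, HSP12 and HSP26, and without 6.5% culture 3 there were 51. Leaving out 0% culture 2 or 3 gave 485 and 754 calls, and scaling the arrays to equal spread gave 307. Of the 68 genes named by the fixed rule 60 were called, of which 58, 44, 12 and 11 were no longer called without 6.5% culture 2, 6.5% culture 3, 0% culture 2 and 0% culture 3. In these fits and those without a swapped array, ADH2 lost its call in 5 of 6, and INA1, NTE1, GAC1, PHO3, HTZ1, CDA1, PAU3, HSP104, TPS1 and RPS3 in 4 of 6. Of the 60 named genes called, 40 lost their call without the dye term, 23 after scaling to equal spread and 18 after quantile normalization.

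**Figure D2:**
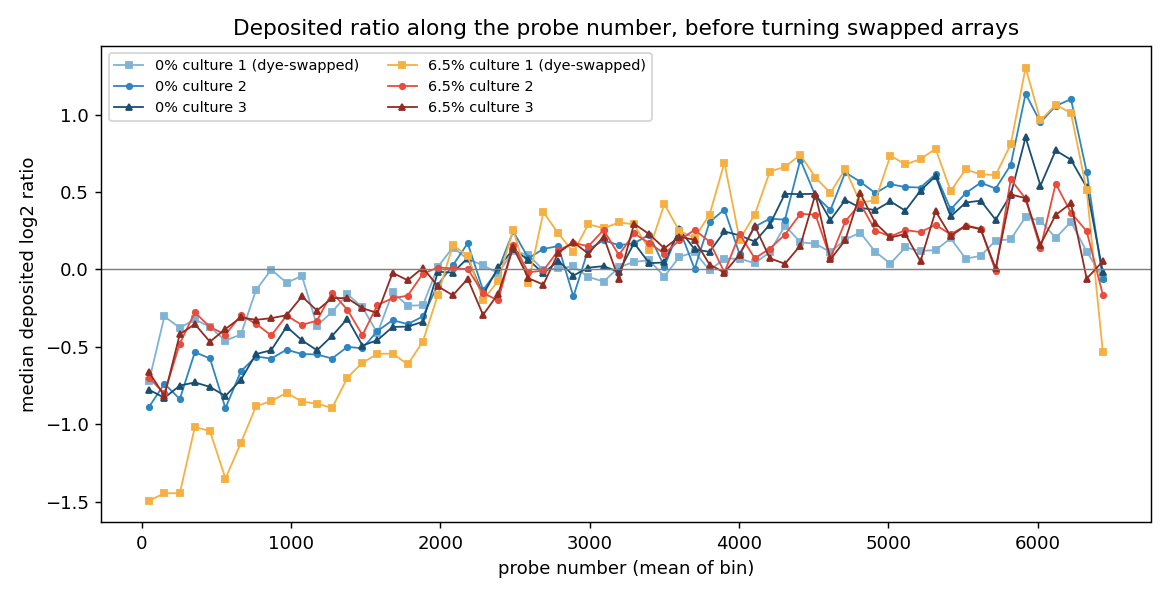
Median deposited log2 ratio (vertical axis) of 64 bins of neighbouring probes against the mean probe number of the bin (horizontal axis), with a line per array, before the swapped arrays were turned. On all 6 arrays the ratio is below 0 at low and mostly above 0 at high probe numbers, and the slope is steepest on the swapped array of 6.5% culture 1.

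Many genes of the protein synthesis machinery fell. Of 136 cytosolic ribosomal protein genes 80 fell, or 105 adjusted over the list alone, and the list's median was −1.10 (camera adjusted p = 1.92e-25, but adjusted p = 0.225 with an estimated correlation). Its lowest members were RPL6B, a protein of the large ribosomal subunit, at −2.62 ± 0.27, and ASC1, a protein of the small subunit that also signals to translation, at −2.47 ± 0.30. RPS3 fell by 1.53 ± 0.33 (adjusted p = 0.0258, and 0.0821 with the trend removed), and RPL3 was at −0.86 ± 0.24 and was not called (adjusted p = 0.0540). Of 129 ribosome biogenesis factors 57 fell (73 adjusted over the list alone), with a median of −0.98 (camera adjusted p = 2.64e-18, and adjusted p = 0.225 with an estimated correlation), led by DBP2 and by the nucleolar protein NSR1 at −2.96 ± 0.40. Of 27 subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, 8 fell (9 adjusted over the list alone, camera adjusted p = 8.29e-04, and adjusted p = 0.225 with an estimated correlation), with RPA190 at −2.46 ± 0.28 and RPA43 at −2.37 ± 0.34. Among 38 translation factors 13 fell and 1 rose (19 and 1 adjusted over the list alone, camera adjusted p = 8.90e-06, and adjusted p = 0.225 with an estimated correlation). EFT2, elongation factor 2, fell by 1.91 ± 0.33 and PRT1, a subunit of initiation factor 3, by 1.88 ± 0.34. The member that rose was GCD6, a subunit of initiation factor 2B, at 1.56 ± 0.33, with an adjusted p of 0.0548 once the trend was removed. In that fit 61 cytosolic ribosomal protein genes and 42 biogenesis factors fell, with medians of −1.03 and −0.95. Of the polymerase subunits 6 fell, and of the translation factors 11.

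Of 31 ergosterol genes 17 fell as well (20 adjusted over the list alone), with a median of −1.11 (camera adjusted p = 9.04e-10, but adjusted p = 0.237 with an estimated correlation). With the trend removed 14 fell, with a median of −0.80. HMG1, which makes the rate-limiting HMG-CoA reductase, fell by 2.99 ± 0.32, the desaturase gene ERG3 by 2.82 ± 0.37 and the methyl oxidase gene ERG25 by 1.94 ± 0.36. ERG25 lost its call in 3 of 6 fits without 1 array, without the dye term (adjusted p = 0.0710), after scaling to equal spread (−1.43, adjusted p = 0.121) and after quantile normalization (−1.44, adjusted p = 0.0903). The list of fatty acid synthesis and desaturation did not pass as deposited (camera adjusted p = 0.0574), with 6 of 21 members lower and 1 higher (6 and 1 adjusted over the list alone). It lay near the threshold. Camera's adjusted p was 0.0418 without the dye term, 0.0486 without 0% culture 2, 0.0438 without 6.5% culture 3 and 0.0319 against the pool alone, but 0.0549 with the trend removed. Of 25 genes of phospholipid and inositol synthesis 4 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.185). INO1, inositol-3-phosphate synthase, was at 1.29 ± 0.59 and was not called (adjusted p = 0.173), with values of 2.89 on 6.5% culture 1 and 0.15 and 0.14 on the others.

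Many stress-inducible genes rose with ethanol. Among 72 genes of the general stress response under the transcription factors Msn2 and Msn4, 33 rose (38 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 2.75e-12, but adjusted p = 0.225 with an estimated correlation). Of 35 heat shock chaperones 15 rose (15 adjusted over the list alone, median 0.60, or 0.52 to 0.93 with 1 array left out and 0.89 with the trend removed, camera adjusted p = 2.81e-07, and adjusted p = 0.225 with an estimated correlation). HSP104, the disaggregase, rose by 1.08 ± 0.28 (adjusted p = 0.0425). HSP30, a membrane heat shock protein, was at −0.03 ± 0.27 (95% interval −0.68 to 0.62) and was not called. With the trend removed HSP30 was at −0.54 (95% interval −1.15 to 0.07), also without a call. Of 26 markers of stationary phase and quiescence 13 rose (15 higher and 1 lower adjusted over the list alone, median 1.48, camera adjusted p = 2.73e-06, and adjusted p = 0.225 with an estimated correlation). HSP12 and HSP26 led all 3 of these lists, which share members. CTT1, cytosolic catalase, belongs to the general stress list and was at −0.70 ± 0.28, without a call (adjusted p = 0.128). In the list of oxidative stress and redox genes 10 of 40 rose and 3 fell (18 and 6 adjusted over the list alone, camera adjusted p = 0.0220, and adjusted p = 0.225 with an estimated correlation). AHP1 led it, followed by the glutaredoxin GRX1 at 2.01 ± 0.28, while CCS1, the copper chaperone of superoxide dismutase, fell by 1.69 ± 0.29.

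Some genes of protein breakdown and recycling rose. Of 42 genes of the proteasome and ubiquitin 9 rose (11 adjusted over the list alone, camera adjusted p = 0.00103, and adjusted p = 0.225 with an estimated correlation), or 5 with the trend removed. The stress-inducible polyubiquitin gene UBI4 rose by 1.59 ± 0.23 and CDC48, an ATPase that extracts ubiquitylated proteins, by 1.58 ± 0.25, with an adjusted p of 0.0549 for CDC48 without the trend. Among 30 autophagy and vacuolar protease genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0106, and adjusted p = 0.237 with an estimated correlation). These included ATG8, a protein of the autophagosome membrane, at 2.36 ± 0.26, and AMS1, the vacuolar mannosidase, at 1.89 ± 0.30.

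In carbon metabolism, 13 of 32 genes of glycolysis and fermentation rose and 1 fell (18 and 5 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 6.42e-04, and adjusted p = 0.237 with an estimated correlation). TDH1 and GPM2 led the list, and ALD6, the cytosolic acetaldehyde dehydrogenase, fell by 1.84 ± 0.25. ADH2, the alcohol dehydrogenase that oxidises ethanol, rose by 1.29 ± 0.36 (adjusted p = 0.0492), but this call was lost in 5 of the 6 fits without 1 array (adjusted p up to 0.155, with changes from 0.95 to 1.63 over the 6). It was also lost without the dye term (adjusted p = 0.155), after scaling to equal spread (0.0936) and after quantile normalization (0.0719). ADH1, the main fermentative isozyme, was at 1.43 ± 0.44 with an adjusted p of 0.0676, and was called with the trend removed (1.81, adjusted p = 0.0377). As deposited it lay between 1.00 and 1.86 with 1 array left out (adjusted p up to 0.225, and 0.0431 without either swapped array). With the trend removed ADH1 was not called without the dye term (adjusted p = 0.133) or without culture 2 or 3 of either group. HXK1, hexokinase 1, was at 0.75 ± 0.27 and was not called (adjusted p = 0.0982). HXT1, a low-affinity glucose transporter, fell by 2.04 ± 0.30 (adjusted p = 0.00984). Of 20 trehalose and glycogen genes 6 rose and 1 fell, or 4 and 1 with the trend removed (as deposited 7 and 1 adjusted over the list alone, camera adjusted p = 0.0128, and adjusted p = 0.264 with an estimated correlation). The trehalase NTH2 rose by 2.10 ± 0.32 and GAC1, which targets a phosphatase to glycogen synthase, by 1.53 ± 0.34, whereas PGM1, the minor phosphoglucomutase, fell by 1.51 ± 0.27. TPS1, trehalose-6-phosphate synthase, rose by 1.38 ± 0.29 (adjusted p = 0.0235), but its adjusted p was 0.112 with the trend removed. GPD1, which makes glycerol in osmotic stress, was at 0.00 ± 0.24 (95% interval −0.56 to 0.57). With the trend removed GPD1 was at −0.49 (95% interval −1.08 to 0.10), and it was called in neither fit. PMA1, the plasma membrane proton pump, was at −1.20 ± 0.44 (adjusted p = 0.104). With 1 array left out PMA1 lay between −1.70 (adjusted p = 0.0416) and −0.75 (adjusted p = 0.281).

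**Figure D3:**
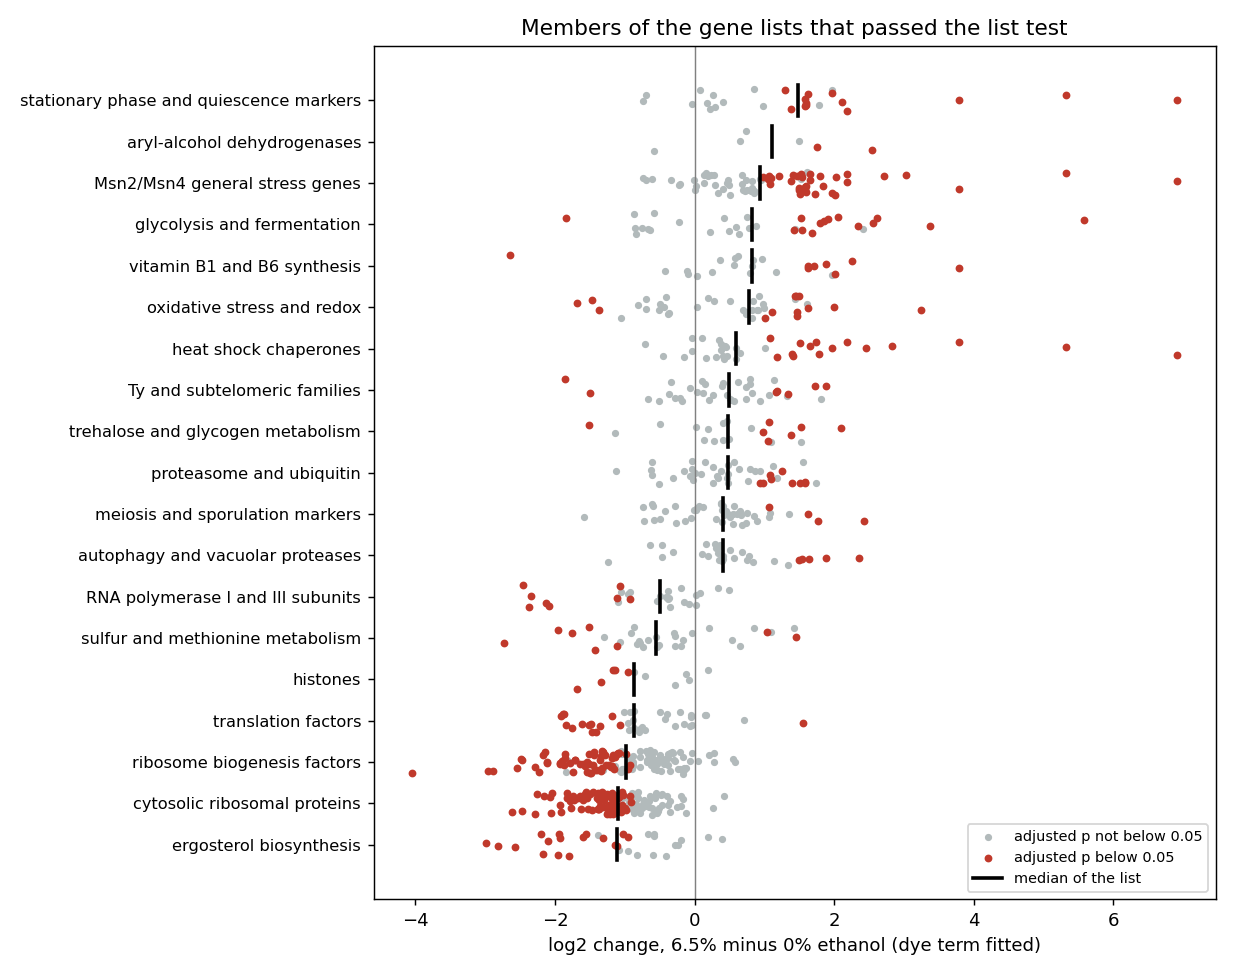
Log2 change from 0% to 6.5% ethanol (horizontal axis) of the members of the 19 gene lists that passed camera with its preset correlation (vertical axis), with a point per gene and a bar at the list's median. As deposited, ergosterol synthesis and cytosolic ribosomal proteins have the lowest medians, −1.11 and −1.10, and the stationary phase markers the highest, 1.48. With the probe-order trend removed the first 2 medians were −0.80 and −1.03.

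Among vitamin genes, 7 of 23 of the thiamine and pyridoxine list rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00103, and adjusted p = 0.225 with an estimated correlation). SNZ1 and THI4, an enzyme of thiamine synthesis, rose, THI4 by 2.26 ± 0.29, while the thiamine-repressed acid phosphatase PHO3 fell by 2.64 ± 0.54. In sulfur and methionine metabolism 6 of 32 genes fell and 2 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.0269, and adjusted p = 0.225 with an estimated correlation). SAM3, which imports S-adenosylmethionine, fell by 2.73 ± 0.40 (with 0% culture 2 at 2.27) and MET14 of sulfate assimilation by 1.95 ± 0.24, while STR2, which converts cysteine to cystathionine, rose by 1.46 ± 0.24. This list did not pass without either swapped array (adjusted p = 0.0592). Of 11 histone genes 5 fell (5 adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.437 with an estimated correlation). The list was not called after scaling to equal spread (adjusted p = 0.117), and its leading members HHO1, linker histone, at −1.68 ± 0.26 and HTZ1, a variant of H2A, at −1.33 ± 0.31 were not called with the trend removed (adjusted p = 0.0567 and 0.138). The list as a whole passed with the trend removed, with 4 members lower (camera adjusted p = 9.19e-04, but adjusted p = 0.293 with an estimated correlation).

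Some small or mixed lists passed with few called members. Of 6 putative aryl-alcohol dehydrogenases AAD6 and AAD4 rose, by 2.54 ± 0.33 and 1.75 ± 0.27 (2 adjusted over the list alone, camera adjusted p = 0.0361, and adjusted p = 0.383 with an estimated correlation). The list did not pass with the trend removed (adjusted p = 0.0549), nor without 0% culture 2 (0.0631) or 6.5% culture 3 (0.0543). Of 38 genes of the PAU, COS and YRF1 families, whose near-identical copies can share probes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0130, and adjusted p = 0.352 with an estimated correlation). COS2 rose by 1.88 ± 0.28 and PAU3 by 1.73 ± 0.43, the latter with an adjusted p of 0.103 once the trend was removed, and YRF1-4 fell by 1.86 ± 0.31. Without 0% culture 2 this list had an adjusted p of 0.0539. Markers of meiosis and sporulation, which a haploid strain does not complete, held 4 of 46 members that rose (3 adjusted over the list alone, camera adjusted p = 0.0473, and adjusted p = 0.233 with an estimated correlation), led by the septin SPR28 at 2.42 ± 0.41 and the chitin deacetylase CDA1 at 1.78 ± 0.36. That list did not pass without either swapped array (0.135) or without 0% culture 3 (0.0705).

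The other 20 lists tested did not pass as deposited. Of 24 genes of the phosphate regulon 1 rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0574), and of 44 G1 and S phase genes 6 fell (6 adjusted over the list alone, 0.0574). These lists passed with the trend removed, at adjusted p = 0.00899 for phosphate and 0.0343 for G1 and S phase, but not with an estimated correlation in that fit (adjusted p = 0.201 for both). In that fit 1 phosphate gene rose and 7 fell, and 3 G1 and S phase genes fell, with a median of −0.17 against −0.36 as deposited. In respiration and carbon use, 8 of 43 oxidative phosphorylation genes rose and 1 fell, 6 of 25 genes of gluconeogenesis and C2 utilisation rose and 3 fell, 2 of 23 genes of the tricarboxylic acid cycle rose and 3 fell, and 2 of 26 hexose transporter genes rose and 4 fell. The counts were 7 higher and 1 lower of 27 for glycerol and osmotic stress, 2 and 3 of 41 for peroxisomes and beta-oxidation, and 3 and 1 of 74 for mitochondrial ribosomal proteins. For biosynthesis and uptake they were 9 and 5 of 66 for amino acids, 5 and 8 of 29 for purines and one-carbon metabolism, and 1 and 3 of 30 for the iron regulon. At the cell surface and in the secretory pathway they were 5 and 13 of 60 for the cell wall, 1 and 7 of 26 for drug resistance and membrane transport, and 5 and 4 of 31 for the unfolded protein response. Of 17 genes of the vacuolar proton pump 2 fell, and of 32 G2, M and early G1 genes 2 rose and 5 fell. Among 27 a-cell and pheromone genes 2 rose and 7 fell. Adjusted over the list alone, the numbers higher and lower were 10 and 3 for oxidative phosphorylation, 8 and 4 for gluconeogenesis, 7 and 2 for glycerol, 13 and 8 for amino acids, 5 and 10 for purines, 5 and 14 for the cell wall, 5 and 5 for the unfolded protein response, and 2 and 6 for G2, M and early G1. They were 0 and 1 for the vacuolar pump and 0 and 0 for peroxisomes and mitochondrial ribosomal proteins, and equal to those over all features for the other lists with counts alone. With the trend removed the numbers higher and lower were 4 and 0 for peroxisomes, 0 and 0 for mitochondrial ribosomal proteins, 4 and 0 for glycerol, 4 and 1 for the unfolded protein response, 3 and 3 for hexose transporters, 1 and 4 for drug resistance, 0 and 4 for G2, M and early G1, and 0 and 5 for a-cell and pheromone genes. The other lists with counts alone changed by at most 2 genes in either direction. As deposited, camera's adjusted p for the lists with counts alone lay between 0.0659 and 0.872. Of the 4 alpha-cell markers, genes of the mating type this strain lacks, none was called, with STE3 at 0.71 ± 0.41, MF(ALPHA)1 at −0.91 ± 0.56, MF(ALPHA)2 at 1.21 ± 0.50 and SAG1 at 0.80 ± 0.37.

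In all, 12 lists were higher and 7 lower at an adjusted p below 0.05 with camera's preset correlation, and 18 of these 19 also passed with the trend removed. With the correlation estimated from the 6 arrays no list passed. The lowest adjusted p was then 0.225, and 6 lists had an unadjusted p below 0.05. A higher correlation was not the sole reason. The sulfur, redox and vitamin lists had estimates of −0.029, −0.009 and −0.011, below the preset 0.01, and still had an adjusted p of 0.225. That setting uses the 3 residual degrees of freedom, so it had little power. For some other lists the estimate was well above the preset. It was 0.606 for histones, 0.341 for aryl-alcohol dehydrogenases, 0.327 for ergosterol and 0.175 for cytosolic ribosomal proteins. The p-values of such lists at the preset correlation may therefore be too small. By fry, which asks whether the genes of a list move one way on balance without setting them against other genes, 29 lists had an adjusted p below 0.05.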

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

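The alternatives that involve the probe-order trend, the arrays that were not swapped or the repeated highest value were chosen after the data were seen, and the others before. Every feature called in the fit to the values as deposited and called again under another setting had the same direction there, and no named gene or list that was called in either fit changed direction. Counts of calls moved widely. As deposited, 1150 features were called, 488 higher and 662 lower. Without the dye term there were 78 (37 and 41), after scaling to equal spread 307 (104 and 203), after quantile normalization 484 (166 and 318) and for the 6.5% arrays against the pool alone 2542 (1283 and 1259). With the trend removed there were 815, with the narrower running median 761 (410 lower), and with the trend removed and no dye term 181 (80 and 101). With the replicate block in place of the dye term there were 607 (250 and 357), and INA1, NTE1, HSP104, TPS1, GAC1, RPS3, ADH2, HTZ1 and PAU3 lost their calls (HSP104 at an adjusted p of 0.0808), and with the trend removed and the block 400 (192 and 208). Same-numbered arrays deviated together (r = 0.70, 0.48 and 0.43 for cultures 1, 2 and 3 across probes), but 0% culture 2 did so more with 6.5% culture 3 (r = 0.51), and number 1 also marks the swapped arrays, so that pairing by number was not established. Leaving out 1 array gave between 2 (without 6.5% culture 2) and 1253 calls (without either swapped array, which gives the same contrast), from 2 to 565 higher and from 0 to 688 lower. At an unadjusted p below 0.05 limma still gave 1552 features without 6.5% culture 2. With the trend removed, leaving out an array gave between 0 calls (without 6.5% culture 2, with 1335 features at an unadjusted p below 0.05) and 1076 (534 higher and 542 lower), with 17 (11 and 6) without 6.5% culture 3, 276 (130 and 146) without 0% culture 2 and 376 (195 and 181) without 0% culture 3. The cause of these shifts was not tested. Every fit without 1 array has the same residual degrees of freedom, so these do not explain the range among such fits. Centring, robust eBayes, array weights, a 2-fold criterion and the other rules on probes kept the counts within 1.5 times. The rules on missing values changed nothing, since none were missing.

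Against 19 lists as deposited, 12 higher and 7 lower, leaving out 1 array gave 18 to 20. This is weak support, since camera with its preset correlation called from 3 to 15 lists in the other splits of the arrays. Those splits hold ethanol and control arrays in both groups, so they are not free of an ethanol effect and do not measure false calls. There were 11 lower lists without the dye term and 11 against the pool alone. With an estimated correlation camera called 0 lists, 0 higher and 0 lower, with 6 at an unadjusted p below 0.05. The cause of these shifts in lists was not tested either. In the alternatives fixed beforehand, a single named gene lost its call in 217 combinations of gene and setting and gained it in 10, and a list lost it in 34 and gained it in 18. Among the added ones these numbers were 248 and 7 for genes and 11 and 28 for lists. Of 2040 such values of named genes 20 had the opposite sign without a call in either fit. Signal over background was not used here, so it is unknown which ratios come from dim spots.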

Other observations

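The tests of isozymes, a-cell-specific genes, probe order and equal highest values were chosen after the results were seen, and the counts over other splits of the arrays were planned. The genes named here were picked after their values were seen, except BAR1, GUA1, HXK1, TDH1 and PGM1.

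Large changes outside the named set are given here by gene, without a claim for their pathways. CYC7, the cytochrome c isoform of low oxygen, rose by 3.03 ± 0.37 (log2, SE, n = 3 per group, adjusted p = 0.00783), the mitochondrial aldehyde dehydrogenase ALD4 by 2.62 ± 0.29, the carnitine acetyltransferase YAT2 by 2.41 ± 0.27, pyruvate carboxylase PYC1 by 2.65 ± 0.25 and ADR1, the activator of ADH2, by 2.35 ± 0.41. NDE1, an external NADH dehydrogenase of mitochondria, fell by 2.59 ± 0.27. All of these were also called with the trend removed. On ALD4 the arrays of 0% cultures 2 and 3 read 2.05 and 1.84 although the pool held RNA of these cultures. On ADR1 the arrays of 0% cultures 1, 2 and 3 likewise departed from the pool, at 0.97, −2.25 and −1.18. The fixed lists of oxidative phosphorylation, gluconeogenesis and C2 utilisation, and the tricarboxylic acid cycle did not pass (camera adjusted p = 0.0659, 0.0845 and 0.809). In pyrimidine synthesis URA1, dihydroorotate dehydrogenase, fell by 2.81 ± 0.28 while URA10, a minor orotate phosphoribosyltransferase, rose by 2.62 ± 0.45. IMD2, the IMP dehydrogenase of guanine nucleotide synthesis, fell by 2.61 ± 0.29, beside GUA1 of the same pathway. The G1 cyclin gene CLN2 fell by 2.38 ± 0.32. Among open reading frames of Ty retrotransposons, YDR261W-B, YBL100W-B, YDR034C-D and YMR051C rose by 3.05 ± 0.49, 2.94 ± 0.28, 2.93 ± 0.39 and 2.23 ± 0.42. Such copies are nearly identical, and whether their probes measured separate transcripts was not tested. The neighbouring unnamed probes 6334, 6335 and 6336 fell by 3.71 ± 0.38, 3.18 ± 0.34 and 4.22 ± 0.33.

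In 14 pairs of isozymes of which 1 is linked to stress or slow growth and the other to growth on glucose, the stress-linked member had the higher change in 12 pairs with the trend removed. The mean difference was 1.49 log2 units (SD 1.33), or 1.225 without the pair of TDH1 and TDH3. That pair had the largest difference, 4.93, and TDH1 holds a repeated highest value on 1 array. CYC7 exceeded CYC1 by 2.65, PGM2 exceeded PGM1 by 2.78, HXK1 exceeded HXK2 by 1.45 and HSP82 exceeded HSC82 by 1.42, while SSE2 against SSE1 and GPX1 against HYR1 went the other way, by −0.12 and −0.38. An exact sign-flip test over the 14 pairs was run (two-sided p = 4.88e-04), but it gives no support, because the pairs were chosen with part of the values known. Whether stress-linked isozymes gained on their partners in general stays open, and paralogues can share probe signal.

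Of 7 a-cell-specific genes BAR1, STE2, MFA1, STE6 and MFA2 fell, by 3.27 ± 0.28, 3.07 ± 0.40, 2.53 ± 0.27, 2.03 ± 0.28 and 1.06 ± 0.26, while AGA2 at −0.13 and ASG7 at −0.19 were not called. The probe-order trend is argued against as the whole cause, since the median of the 7 genes was −2.03 with the trend removed, where MFA2 alone of the 5 lost its call because its estimate shrank at an unchanged SE (−0.61 ± 0.26, adjusted p = 0.170). Replacement of most cells by alpha cells would bring much RNA of the abundant MF(ALPHA)1, but the upper 95% limit of its change was 0.875 with the trend removed. This marker is itself doubtful, since it read 2.37 on 0% culture 2 although the pool held RNA of that culture. A share of alpha cells stays open, since MF(ALPHA)2, SAG1 and STE3 were at 1.29 (95% interval 0.06 to 2.51), 0.89 (0.12 to 1.67) and 0.76 (−0.15 to 1.67), none of them called. Diploid cells would lack the haploid-specific transcripts as well, but all 8 of GPA1, STE4, STE18, STE5, FUS3, RME1, FAR1 and STE12 had 95% intervals above the median of the a-specific genes, although FAR1 fell by 1.41 ± 0.24 and STE12 by 0.99 ± 0.26 (with the trend removed by 1.19 and 0.79, adjusted p = 0.0266 and 0.113), so that lower a-specific expression in ethanol stays a hypothesis, with time in culture and growth phase untested.

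The tilt of calls along the probe number bears on the counts of calls. The deposited ratios rose with probe number on every array, with a lowest rho of 0.223, as a bias by dye and print order or spot layout would give. After turning, the swapped 6.5% array was at rho = −0.516 and 6.5% cultures 2 and 3 at 0.24 and 0.22. This shared slope dominates single arrays, so these values cannot decide on a difference between cultures by chromosome. Such a difference stays open. In the tenth of probes with the lowest numbers, the deposited medians of the swapped arrays were −1.27 at 6.5% and −0.40 at 0%. Those of cultures 2 and 3 were −0.50 and −0.50 at 6.5%, and −0.73 and −0.76 at 0%. After turning, the 6.5% minus 0% difference there thus had the same direction in both dye orientations. In simulated data without an ethanol effect, these trends alone gave at most 2 calls in 20 data sets. Without real changes the adjusted threshold is stricter than in the data, so this cannot show how many calls the tilt made there. The 19 features of the mitochondrial genome, which lie next to each other, had a median change of 1.10 as deposited and 0.20 with the trend removed, and these data do not show which is nearer to the truth.

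On the array of 0% culture 1 the highest value, 4.61, occurred on 19 probes, whereas the highest value of each other array occurred once. A candidate explanation is a fault tied to the layout of the array, since 7 pairs of these probes lay 6 probe numbers apart, against at most 3 pairs at any 1 distance in 10000 random draws (distances up to 50 searched in each, permutation p = 1e-04, one-sided, the smallest these draws can give). The gene affected among those named is TDH1. With these values set to missing 1178 features were called.

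The 6 arrays can be split into groups of 3 in 10 ways, too few for a share below 0.05. Only 1 split, the real one, gave as many calls as the 1150 found, or as the 815 with the trend removed. The highest of the others was 0 calls by limma in both cases, with up to 409 and 449 features at an unadjusted p below 0.05 against 2237 and 1984 in the real split. For gene lists, 1 split, again the real one, gave 19, and the highest of the others gave 15. The other splits mix ethanol and control arrays in both groups. An ethanol effect then enters both their contrasts and their residuals, so their counts do not measure false calls.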
